A study of Homo sapiens with 36 samples.

How the data were processed

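RNA sequencing counts from 36 libraries of iPSC-derived sensory neurons were analysed. The cells had been kept in DMEM/F12 with N2, B27, 25 ng/mL each of BDNF, GDNF, NT-3 and beta-NGF, and 1 µM of PD0332991, an inhibitor of cell cycle kinases. RNA was taken with RNeasy Plus Micro columns, and stranded TruSeq libraries were sequenced from both ends. Per the labels, the authors made the base calls with bcl2fastq 2.20, aligned the reads to hg38 with STAR and counted them with HTSeq. The versions of STAR and HTSeq, the annotation release and the strand setting of the counting are not stated. The deposited values are counts per gene and library, whole numbers that were not normalised. A further deposited table of 48 columns belongs to samples outside the sample list and was not used. Gene positions come from GENCODE 29 on GRCh38, joined by gene identifier for 99.4% of the 58278 genes.

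The 2 technical libraries of each biological replicate were summed to 18 samples, 3 per group. Genes with low counts were removed with filterByExpr at its defaults, which left 24440, and libraries were scaled by TMM. The quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) was run on all 6 groups with the group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with 0.05 as the threshold. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The comparisons were paclitaxel against vehicle without inhibitor and under each inhibitor, each inhibitor against none with and without paclitaxel, both interactions, and GNE-495 + PTX against JNK-IN-8 + PTX, 10 in all. CPM values are normalised by TMM. Samples with the same replicate number share a labelled batch. Pairing was checked by correlating the samples' deviations from their group means: r lay between 0.31 and 0.52 for 45 sample pairs with the same number and between −0.38 and 0.01 for 90 pairs with different numbers. The same fit was therefore also made with the batch as a block, which lowered the common biological coefficient of variation from 0.176 to 0.0689.

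The lists comprised 31 sets of 526 entries: axon injury response, AP-1 factors, MAPK feedback genes, immediate early genes, p53 targets, intrinsic apoptosis, integrated stress response, ER chaperones, heat shock genes, NRF2 targets, tubulins, microtubule-associated proteins, axonal transport motors, neurofilament and axon cytoskeleton, axon degeneration and NAD, MAP4K and JNK cascade, sensory neuron identity, voltage-gated channels, synaptic vesicle genes, cholesterol synthesis, YAP-TEAD targets, Wnt targets, lysosome and autophagy genes, inflammatory cytokines, interferon-stimulated genes, mitochondrially encoded genes, glial and Schwann cell markers, mesenchymal markers, proliferation markers, progenitor and pluripotency markers, and melanocyte markers. They were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the lists within a comparison, with an estimated correlation and fry as alternatives. Named genes were, per pair of groups, the 8 largest rises and 8 largest falls among genes that passed with a mean log2 CPM of at least 1 and the same sign in all 3 batches, and 5 each for the interactions and the comparison of inhibitors. Up to 4 members of each list with the smallest p were added, and 18 genes were named whatever their values, some being left out for length. The comparisons, lists, rule for named genes and most alternatives were fixed before the data were examined.

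The alternatives were DESeq2 1.42.0, its size factors within edgeR, other filters on low counts, the groups of a comparison alone, each library as a sample, 1 technical library per replicate, a minimum log2 fold change of 1, and leaving out each replicate. The steps were tested on simulated data with the gene means, batch shifts and depths of these samples, in which 50 genes for each of 4 effect sizes (log2 of 0.5, 1, 1.5 and 2) were changed in the paclitaxel group and 13 tubulin genes raised by 0.5, whose calls are in the totals. The test without the block recovered 48, 90, 90 and 100% of them with 0 false calls of 166. With the block it recovered 88, 100, 100 and 100% with 12 false calls of 218, and DESeq2 64, 94, 96 and 100% with 2 of 185. Figures were drawn with matplotlib 3.10.9. The p-values measure the spread between these samples alone: the replicates are batches of 1 cell line, so they say nothing of other lines or donors.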

Results

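RNA was sequenced from human sensory neurons derived from GR1.1, an induced pluripotent stem cell line supplied by Lonza, after 28 days in vitro. Cultures were treated for 24 hours with the vehicle (0.1% DMSO, labelled DMSO), with 0.3 µM paclitaxel (PTX), a chemotherapy drug that stabilises microtubules and injures sensory axons, or with a kinase inhibitor with or without paclitaxel. GNE-495, given at 3 µM, inhibits the MAP4K branch of the STE20 kinases, which act upstream of the kinase JNK. JNK-IN-8, also at 3 µM, is a covalent JNK inhibitor. Per the series description, the first compound was used to protect axons and the second to protect the cells from dying. Each of the 6 groups (DMSO, PTX, GNE-495 + DMSO, GNE-495 + PTX, JNK-IN-8 + DMSO, JNK-IN-8 + PTX) had 3 biological replicates, which the labels call batches 1 to 3, and 2 technical libraries per replicate, 36 libraries in all.

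The libraries held between 35452116 and 50073592 counts, except 1 library of JNK-IN-8 + PTX (batch 3, technical replicate 2) with 7448989, called the shallow library here. In it 2.14% of counts came from mitochondrially encoded genes, against 0.205 to 0.445% in the others. The technical libraries were summed to 18 samples of 49492410 to 99318828 counts, and 24440 of 58278 genes were tested. The first principal component (29.7% of the variance) parted the samples with JNK-IN-8 from the rest, and the second (17.7%) parted batch 2 from batches 1 and 3. Gene values below are log2 fold changes ± standard error with n = 3 samples per group. List values are medians of the members' log2 fold changes ± SD over the 3 batches. Values "with the block" come from the fit in which the batch is held constant, and they are given where they change a call or move a count by more than 1.5 times. Genes named for passing with the block without p-values of both fits carry the value and error of that fit. Where a list's count is given for 1 direction, no member passed in the other. Counts "without replicate 1" leave that batch out of every group, and those without a replicate of a named group leave out that sample.

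**Figure D1:**
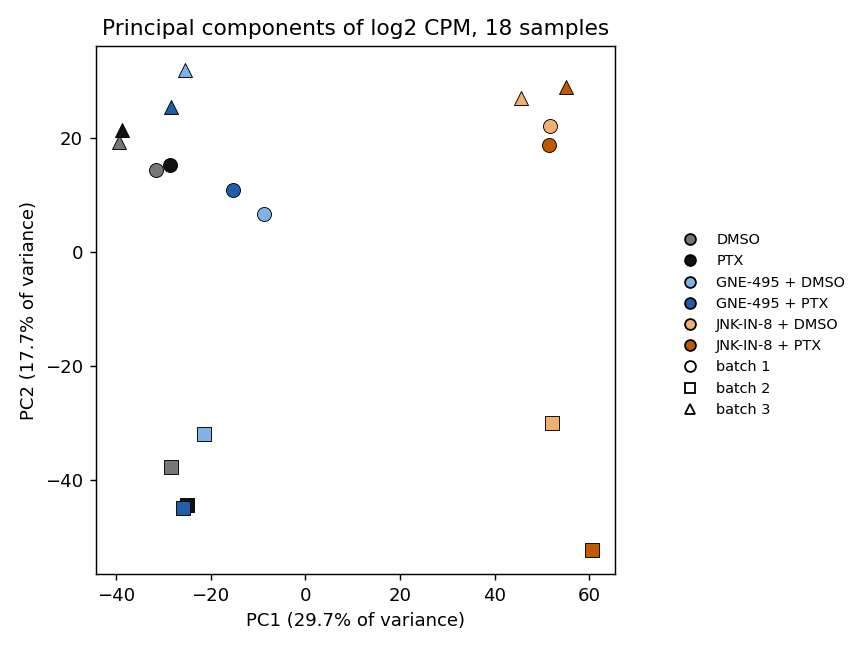
Position of each of the 18 samples on the first and second principal components of log2 CPM, with the percent of variance on each axis, 1 point per sample, colour for the treatment and shape for the batch. Samples with JNK-IN-8 lie on the right, and batch 2 lies low on the second axis in every treatment.

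Paclitaxel against vehicle showed what the drug alone did to the cultures' transcripts. Tubulin transcripts were higher by modest amounts. TUBB4B, a beta-tubulin isotype, rose from 163 ± 29.9 to 294 ± 25.7 CPM (SD, n = 3), a log2 fold change of 0.85 ± 0.11 (adjusted p = 0.0119). ACAT2, the enzyme that joins acetyl-CoA units at the start of the mevalonate pathway, fell from 143 ± 25.9 to 74.5 ± 5.72 CPM, a change of −0.94 ± 0.12 (adjusted p = 0.0119). HRK, a BH3-only protein that promotes neuronal apoptosis, had 10.7 ± 1.25 CPM in vehicle and 19.2 ± 1.74 CPM in paclitaxel, and CASP3, an executioner caspase, 80.4 ± 4.96 and 107 ± 6.55 CPM. These passed only with the block: HRK (0.84 ± 0.18, adjusted p = 0.296, 0.00157 with the block) and CASP3 (0.42 ± 0.08, adjusted p = 0.223, 0.000512 with the block). In GRCh38 (GENCODE 29) the genes are TUBB4B (ENSG00000188229.5, chromosome 9 from 137241213 to 137243707, plus strand), ACAT2 (ENSG00000120437.8, chromosome 6 from 159760328 to 159779055, plus strand), HRK (ENSG00000135116.9, chromosome 12 from 116856144 to 116881441, minus strand) and CASP3 (ENSG00000164305.18, chromosome 4 from 184627696 to 184649509, minus strand).

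Among the 13 tubulin genes measured, 1 rose over all genes, 11 adjusted over the list alone and 11 with the block, and the list median was 0.47 ± 0.16 (camera adjusted p = 7.45e-36). TUBB (0.69 ± 0.08), TUBB3 (0.53 ± 0.06), the neuronal beta-tubulin, and TUBA1B (0.71 ± 0.11) passed with the block (adjusted p = 0.000473, 0.000306 and 0.00435). Reads of tubulin genes can be shared between the copies and their pseudogenes, so the value of a single tubulin gene is uncertain. For cholesterol synthesis, of 23 genes 1 fell over all genes, 6 adjusted over the list alone and 12 with the block. Their median was −0.31 ± 0.13 (camera adjusted p = 1.08e-19, adjusted p = 0.278 with an estimated correlation). LSS (−0.48 ± 0.06), FDFT1 (−0.42 ± 0.07) and MVD (−0.53 ± 0.08), enzymes of the same pathway, passed with the block. Glial and Schwann cell markers had a median of 0.36 ± 0.12, and of 10 genes 0 rose over all genes in edgeR, 6 adjusted over the list alone and 6 with the block (camera adjusted p = 1.05e-11, adjusted p = 0.0514 with an estimated correlation). Their members included FABP7 (0.54 ± 0.12) and MPZ (0.45 ± 0.07), which passed with the block.

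Higher medians were found for ER chaperones (16 measured, median 0.13, camera adjusted p = 4.57e-05, adjusted p = 0.417 with an estimated correlation) and proliferation markers (12 measured, median 0.41, camera adjusted p = 0.000244, adjusted p = 0.478 with an estimated correlation). Lower medians were found for NRF2 targets (16 measured, median −0.18, camera adjusted p = 0.000124, adjusted p = 0.391 with an estimated correlation), integrated stress response genes (23 measured, median −0.21, camera adjusted p = 0.0178, adjusted p = 0.705 with an estimated correlation) and heat shock genes (13 measured, median −0.07, camera adjusted p = 0.0089, adjusted p = 0.278 with an estimated correlation). They were also lower for neurofilament and axon cytoskeleton genes (11 measured, median −0.13, camera adjusted p = 0.00149, adjusted p = 0.278 with an estimated correlation), microtubule-associated proteins (20 measured, median −0.12, camera adjusted p = 0.00316, adjusted p = 0.563 with an estimated correlation), axonal transport motors (20 measured, median −0.07, camera adjusted p = 0.0278, adjusted p = 0.563 with an estimated correlation) and synaptic vesicle genes (19 measured, median −0.10, camera adjusted p = 0.0206, adjusted p = 0.627 with an estimated correlation). Sensory neuron identity genes (22 measured, median −0.11) and melanocyte markers (4 measured, median 0.57) passed only with the block, with camera adjusted p = 0.051 and 0.0517 without it and 0.00227 and 0.0248 with it. Axon injury genes (median −0.08, camera adjusted p = 0.327), p53 targets (0.02, camera adjusted p = 0.638) and intrinsic apoptosis genes (−0.02, camera adjusted p = 0.291) did not pass. For apoptosis genes the median lay below 0 while the mean (0.06) and the test lay above it. The injury genes JUN (0.08 ± 0.14), ATF3 (−0.15 ± 0.49) and GAP43 (−0.18 ± 0.09) did not pass.

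In all 2 genes passed, 1 up and 1 down, and 478 passed with the block, 274 up and 204 down, the 2 among them. With the block, the largest rises included KCNJ13 (1.32 ± 0.21), a potassium channel, FGFR3 (1.07 ± 0.20), a fibroblast growth factor receptor, and CHL1 (0.90 ± 0.11), a cell adhesion molecule. The largest falls included ASS1 (−1.04 ± 0.18), argininosuccinate synthase, and SERPINE1 (−0.93 ± 0.17), the plasminogen activator inhibitor. The choice of these 5 genes from the blocked fit was made after the values were seen. The count was 0 without DMSO replicate 1, PTX replicate 1, PTX replicate 3, replicate 1 or replicate 3, 1 without PTX replicate 2, 5 without DMSO replicate 3 and 54 without replicate 2. These counts are edgeR's. In the full data 1111 of 24440 genes had an unadjusted p under 0.05, fewer than chance gives (3384 with the block). Batch differences left in the error can cause this, here and below, so it does not show a lack of effect.

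GNE-495 against vehicle showed the effect of the STE20 inhibitor without paclitaxel. Cholesterol synthesis genes rose strongly. The largest rises were in PLA2G3 (3.71 ± 0.40), a secreted phospholipase, GDA (3.64 ± 0.22), guanine deaminase, LIPG (3.46 ± 0.33), endothelial lipase, and PCSK9 (2.98 ± 0.42), which sends the LDL receptor to degradation. FABP3 (2.94 ± 0.51), SLCO4C1 (2.71 ± 0.43), TMEM97 (2.30 ± 0.16) and STARD4 (2.27 ± 0.19) followed, the last a sterol carrier. LIF, a cytokine of the injury response, fell most (−1.96 ± 0.37), with SERPINE1 (−1.36 ± 0.23), ARSI (−1.16 ± 0.17), a sulfatase, and EGR1 (−1.14 ± 0.27, adjusted p = 0.0475, 0.0507 with the size factors of DESeq2, 0.0732, 0.254 and 0.438 without replicate 1, 2 or 3), an immediate early transcription factor.

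ACAT2 rose from 143 ± 25.9 to 493 ± 29.6 CPM (SD, n = 3). Of 23 cholesterol synthesis genes, 22 rose over all genes and 23 adjusted over the list alone. The median of the list was 1.36 ± 0.25 (camera adjusted p = 2.28e-165). ACAT2 (1.78 ± 0.12), LSS (1.57 ± 0.12) and FDFT1 (1.36 ± 0.13) were examples. NRF2 targets, genes of the antioxidant response, had a median of 0.42 ± 0.11. Of 16 members, 5 rose over all genes, 9 adjusted over the list alone and 12 with the block (camera adjusted p = 3.62e-17), among them ME1 (1.18 ± 0.13), G6PD (0.58 ± 0.07) and NQO1 (0.87 ± 0.17). For lysosome and autophagy genes the median was 0.16 ± 0.06 (camera adjusted p = 2.57e-06, adjusted p = 0.31 with an estimated correlation). Of their 22 members, 1 rose and 0 fell over all genes, 4 and 1 adjusted over the list alone, and 11 and 1 with the block. NEU1, a lysosomal sialidase, was the member that rose (0.87 ± 0.15).

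Of 10 inflammatory cytokine genes, 1 fell over all genes, 3 adjusted over the list alone and 3 with the block. The list median was −0.37 ± 0.15 (camera adjusted p = 7.89e-05). CXCL8 (−1.23 ± 0.41) and IL11 (−1.05 ± 0.27) had adjusted p = 0.229 (0.0229 with the block) and 0.067 (0.000229 with the block). Among 14 immediate early genes, 1 fell over all genes, 4 adjusted over the list alone and 6 with the block. Their median was −0.39 ± 0.20 (camera adjusted p = 7.85e-05, adjusted p = 0.102 with an estimated correlation). Wnt targets had a median of −0.26 ± 0.08 (camera adjusted p = 0.00335). Of these 12 genes, 0 fell over all genes in edgeR, 3 adjusted over the list alone and 5 with the block, led by NKD1 (−0.73 ± 0.11), SP5 (−0.84 ± 0.18) and AXIN2 (−0.43 ± 0.12), feedback regulators of the pathway that passed with the block. YAP-TEAD targets had a median of −0.31 ± 0.21 (camera adjusted p = 0.00113, adjusted p = 0.48 with an estimated correlation). Of the 22 members, 1 fell over all genes, 1 adjusted over the list alone and 8 with the block, with AMOTL2 (−0.45 ± 0.08) as the member that fell. Axon injury genes had a median of −0.19 ± 0.12 (camera adjusted p = 0.0227, adjusted p = 0.31 with an estimated correlation). Of their 23 genes, 0 rose and 1 fell over all genes, 2 and 6 adjusted over the list alone, and 2 and 8 with the block.

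CASP3 fell (−0.56 ± 0.09), and among 20 apoptosis genes 0 rose and 1 fell over all genes, 0 and 3 adjusted over the list alone, and 1 and 4 with the block. The median of the list was −0.04 ± 0.08 (camera adjusted p = 0.0378, 0.0797 with the block, adjusted p = 0.31 with an estimated correlation). HRK was 6.31 ± 1.84 CPM, a difference of −0.76 ± 0.18 from vehicle (adjusted p = 0.0515, 0.000259 with the block). Tubulins had a median of 0.29 ± 0.21 (camera adjusted p = 1.24e-06, adjusted p = 0.22 with an estimated correlation). Of these 13 members, 0 rose over all genes in edgeR, 5 adjusted over the list alone and 8 with the block. Glial and Schwann cell markers had a median of 0.30 ± 0.04 (camera adjusted p = 0.000126, adjusted p = 0.232 with an estimated correlation). Of the 10 genes, 1 rose over all genes, 1 adjusted over the list alone and 4 with the block, the member that rose being FABP7 (1.21 ± 0.13). Voltage-gated channel genes had a median of −0.13 ± 0.01 (camera adjusted p = 0.0324, adjusted p = 0.599 with an estimated correlation). Of their 22 members, 0 fell over all genes in edgeR, 0 adjusted over the list alone and 6 with the block. Mitochondrially encoded genes had a median of 0.18 ± 0.27 (camera adjusted p = 0.0284, 0.081 with the block, adjusted p = 0.632 with an estimated correlation), and none of the 13 passed in edgeR with or without the block. Integrated stress response genes had a median of 0.15 (camera adjusted p = 0.117, 0.020 with the block). Further falls were found in MET (−0.98 ± 0.19), PMEPA1 (−0.87 ± 0.16) and GABRG2 (−0.77 ± 0.16), coding for the hepatocyte growth factor receptor, a TGF-beta-induced protein and a GABA receptor subunit, and in RP11-54O7.1 (−0.78 ± 0.18), a gene without an assigned function.

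The comparison called 391 genes, 305 up and 86 down (78.0% up), and with the block 2063, 1109 up and 954 down (53.8% up). The count was 96 (94 up and 2 down) without replicate 3, 101 (95 up and 6 down) without replicate 1, 243 without GNE-495 + DMSO replicate 3, 249 without DMSO replicate 2 and 257 without DMSO replicate 1. Of the falls named above, ARSI alone passed without replicate 1 (adjusted p = 0.0429) and CASP3 alone without replicate 3 (0.0229).

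**Figure D2:**
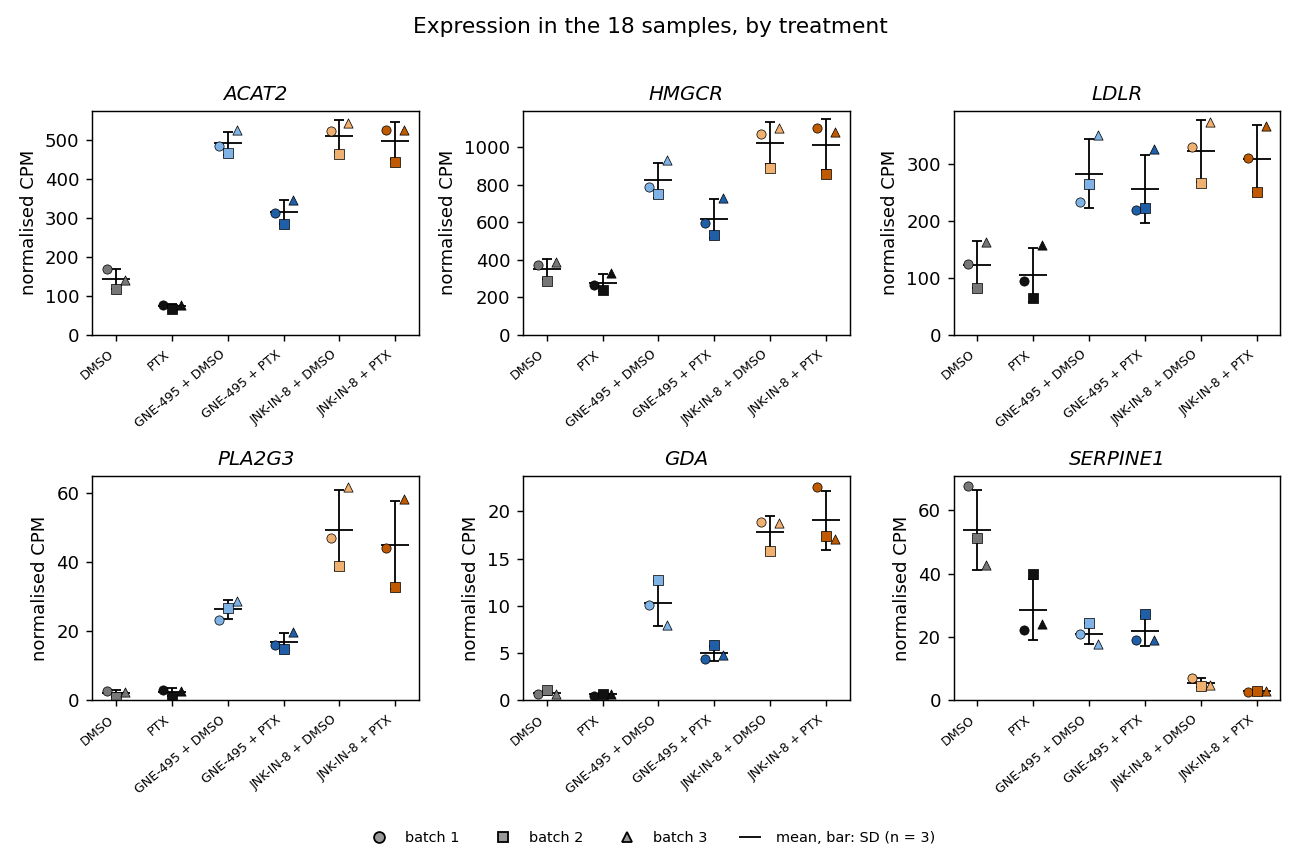
Normalised CPM of 6 genes in the 18 samples, by treatment, each point a sample with its shape for the batch, bars the mean and SD (n = 3). ACAT2, HMGCR, LDLR, PLA2G3 and GDA lie higher and SERPINE1 lower in the groups with GNE-495 or JNK-IN-8 than in the matching groups without inhibitor.

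JNK-IN-8 against vehicle showed the effect of the JNK inhibitor without paclitaxel. Its largest rises included PLA2G3 (4.62 ± 0.42), GDA (4.43 ± 0.22), PCSK9 (4.10 ± 0.43), SLCO4C1 (3.90 ± 0.45), LIPG (3.82 ± 0.34) and TMEM97 (3.00 ± 0.16). DERL3 (3.39 ± 0.15), a factor of ER-associated degradation, and KCNJ10 (2.88 ± 0.30), an inwardly rectifying potassium channel, also rose. CLDN4 (−4.32 ± 0.42), a tight junction protein, TNFRSF12A (−3.49 ± 0.28), a receptor induced by nerve injury, and SERPINE1 (−3.27 ± 0.25) fell most, with LINC00346 (−3.23 ± 0.30), ITGB8 (−3.23 ± 0.40), MSTN (−3.14 ± 0.36) and ARSI (−3.13 ± 0.18). KRTAP5-AS1 (−3.12 ± 0.18) is an antisense gene, and the strand setting of the counting is not stated, so its value is uncertain. In GRCh38 (GENCODE 29) the genes are PLA2G3 (ENSG00000100078.3, chromosome 22 from 31134809 to 31140607, minus strand), GDA (ENSG00000119125.16, chromosome 9 from 72114595 to 72257193, plus strand), CLDN4 (ENSG00000189143.9, chromosome 7 from 73799542 to 73832693, plus strand) and TNFRSF12A (ENSG00000006327.13, chromosome 16 from 3018445 to 3022383, plus strand).

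JUN, the transcription factor that JNK phosphorylates, fell from 98.1 ± 8.82 to 47.2 ± 2.07 CPM (−1.06 ± 0.14), and HRK from 10.7 ± 1.25 to 2.58 ± 0.271 CPM (−2.05 ± 0.19). Of 23 axon injury genes, 2 rose and 9 fell over all genes, and 2 and 10 adjusted over the list alone. The list median was −0.14 ± 0.10 (camera adjusted p = 0.000451, adjusted p = 0.14 with an estimated correlation). Of 15 AP-1 factors, 1 rose and 5 fell over all genes, 1 and 6 adjusted over the list alone, and 2 and 6 with the block. Their median was −0.10 ± 0.20 (camera adjusted p = 0.0484, adjusted p = 0.189 with an estimated correlation), JUND (−1.03 ± 0.10) and FOSL1 (−1.93 ± 0.35) falling and FOSB (1.92 ± 0.43) rising. Of 20 apoptosis genes, 2 rose and 5 fell over all genes, 2 and 5 adjusted over the list alone, and 3 and 8 with the block. The median of the list was −0.08 ± 0.03 (camera adjusted p = 0.042, adjusted p = 0.319 with an estimated correlation). CASP3 (−0.89 ± 0.09) and CASP7 (−1.19 ± 0.13) fell while BCL2L11 (1.84 ± 0.16), coding for the BH3-only protein BIM, rose. Inflammatory cytokine genes had a median of −1.19 ± 0.16 (camera adjusted p = 1.61e-06). Of these 10 genes, 6 fell over all genes and 6 adjusted over the list alone, led by CXCL8 (−3.66 ± 0.50), LIF (−2.45 ± 0.38) and IL11 (−1.74 ± 0.28).

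In cholesterol synthesis, 23 rose over all genes and 23 adjusted over the list alone. The list median was 1.55 ± 0.07 (camera adjusted p = 2.68e-53), ACAT2 reaching 511 ± 41.2 CPM. NRF2 targets had a median of 0.54 ± 0.11 (camera adjusted p = 4.41e-09, adjusted p = 0.168 with an estimated correlation). Of the 16 members, 10 rose and 0 fell over all genes, 10 and 0 adjusted over the list alone, and 12 and 1 with the block, with NQO1 (1.70 ± 0.17), ME1 (1.47 ± 0.13) and GCLM (1.18 ± 0.13) as examples. Wnt targets had a median of 0.78 ± 0.08 (camera adjusted p = 0.0221, adjusted p = 0.116 with an estimated correlation). Of their 12 genes, 6 rose and 0 fell over all genes, 6 and 0 adjusted over the list alone, and 8 and 1 with the block, with SP5 (1.49 ± 0.26), AXIN2 (0.70 ± 0.15) and NKD1 (0.89 ± 0.20). Glial and Schwann cell markers had a median of 0.49 ± 0.08 (camera adjusted p = 1.5e-07, adjusted p = 0.116 with an estimated correlation). Of these 10 members, 6 rose and 0 fell over all genes, 7 and 0 adjusted over the list alone, and 9 and 1 with the block, with FABP7 (2.15 ± 0.14), MBP (1.77 ± 0.32) and SOX10 (0.40 ± 0.07). Integrated stress response genes had a median of 0.44 ± 0.26 (camera adjusted p = 0.0175, adjusted p = 0.805 with an estimated correlation). Of the 23 genes, 3 rose over all genes, 3 adjusted over the list alone and 13 with the block, with VLDLR (1.20 ± 0.12), PHGDH (0.95 ± 0.24) and DDIT4 (0.78 ± 0.24). Synaptic vesicle genes had a median of 0.16 ± 0.11 (camera adjusted p = 0.125, 0.00915 with the block). Of their 19 members, 5 rose and 1 fell over all genes, 5 and 1 adjusted over the list alone, and 9 and 3 with the block, with SV2A (1.03 ± 0.16) and SNCA (0.74 ± 0.16).

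Tubulins had a median of −0.33 ± 0.19 (camera adjusted p = 0.000451, adjusted p = 0.379 with an estimated correlation). Of these 13 genes, 7 fell over all genes and 7 adjusted over the list alone, TUBB6 (−1.60 ± 0.19) and TUBA1B (−0.97 ± 0.15) among those that fell. Proliferation markers had a median of −0.87 ± 0.43 (camera adjusted p = 0.00641, adjusted p = 0.641 with an estimated correlation). Of the 12 members, 6 fell over all genes and 6 adjusted over the list alone, with BIRC5 (−1.33 ± 0.31) and MKI67 (−1.27 ± 0.35). YAP-TEAD targets had a median of −0.44 ± 0.04 (camera adjusted p = 0.020, adjusted p = 0.641 with an estimated correlation). Of their 22 genes, 3 rose and 6 fell over all genes, 3 and 7 adjusted over the list alone, and 4 and 13 with the block, with AMOTL2 (−0.81 ± 0.08), AXL (−0.76 ± 0.11) and NUAK2 (−1.31 ± 0.23). MAPK feedback genes had a median of −0.07 ± 0.08 (camera adjusted p = 0.147). Of these 19 members, 6 rose and 6 fell over all genes, and 7 and 6 adjusted over the list alone, with DUSP16 (−2.78 ± 0.18), DUSP8 (−2.07 ± 0.18) and SPRY1 (−1.52 ± 0.12) among those that fell. Among sensory neuron identity genes 5 rose and 3 fell over all genes, 5 and 3 adjusted over the list alone, and 9 and 7 with the block, with ISL1 (0.62 ± 0.09) and POU4F1 (0.52 ± 0.13), sensory transcription factors, and TAC1 (−1.55 ± 0.24), the substance P precursor. Their median (0.12) and test lay above 0 and their mean (−0.15) below it (camera adjusted p = 0.655). In all 5199 genes passed, 2495 up and 2704 down, and with the block 9369, 4631 up and 4738 down. The count was 1908 without replicate 3 and 2508 without replicate 1.

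GNE-495 + PTX against GNE-495 + DMSO showed the paclitaxel effect in the presence of the STE20 inhibitor. CASP3 rose (0.63 ± 0.09, adjusted p = 0.00558, and 0.464, 0.146 and 0.164 without replicate 1, 2 or 3), from 54.6 ± 5.24 to 84.4 ± 6.25 CPM (SD, n = 3), and was the 1 gene up. The genes that fell most were RASA4CP (−1.43 ± 0.20), a pseudogene whose reads can come from its parent gene, PRUNE2 (−1.28 ± 0.20), DERL3 (−1.22 ± 0.14), ZNF442 (−0.97 ± 0.16), a zinc finger gene, and TMEM97 (−0.92 ± 0.15), a sterol-regulated membrane protein. NCR3LG1 (−0.90 ± 0.13), FLVCR1 (−0.71 ± 0.09), a heme and choline transporter, and its antisense neighbour FLVCR1-AS1 (−0.70 ± 0.09) followed.

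HRK had 6.31 ± 1.84 CPM without and 10.8 ± 0.815 CPM with paclitaxel, and passed with the block: HRK (0.77 ± 0.18, adjusted p = 0.217, 0.000934 with the block). Of 20 apoptosis genes, 1 rose and 0 fell over all genes, 2 and 1 adjusted over the list alone, and 2 and 1 with the block. Their median was −0.02 and their mean 0.05, the test pointing up (camera adjusted p = 0.307). Tubulins had a median of 0.25 ± 0.02 (camera adjusted p = 1.08e-13, adjusted p = 0.194 with an estimated correlation). Of the 13 genes, 0 rose over all genes in edgeR, 5 adjusted over the list alone and 4 with the block, with TUBB4B (0.60 ± 0.09) and TUBB3 (0.33 ± 0.06) among the members that passed with the block. Cholesterol synthesis genes had a median of −0.28 ± 0.07 (camera adjusted p = 9.3e-18, adjusted p = 0.279 with an estimated correlation). Of their 23 members, 0 fell over all genes in edgeR, 2 adjusted over the list alone and 9 with the block, with ACAT2 (−0.65 ± 0.07) and STARD4 (−0.74 ± 0.10) passing with the block. NRF2 targets had a median of −0.18 ± 0.02 (camera adjusted p = 3.59e-11, adjusted p = 0.256 with an estimated correlation). Of these 16 genes, 0 fell over all genes in edgeR, 3 adjusted over the list alone and 4 with the block. Glial and Schwann cell markers had a median of 0.12 ± 0.10 (camera adjusted p = 0.0446, adjusted p = 0.638 with an estimated correlation), and none passed in edgeR with or without the block.

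Lower medians were also found for integrated stress response genes (23 measured, median −0.28, camera adjusted p = 6.18e-05, adjusted p = 0.666 with an estimated correlation), axonal transport motors (20 measured, median −0.09, camera adjusted p = 0.000585, adjusted p = 0.444 with an estimated correlation) and neurofilament and axon cytoskeleton genes (11 measured, median −0.08, camera adjusted p = 0.00019, adjusted p = 0.265 with an estimated correlation). The same held for axon degeneration and NAD genes (13 measured, median −0.08, camera adjusted p = 0.021, adjusted p = 0.256 with an estimated correlation) and microtubule-associated proteins (20 measured, median −0.06, camera adjusted p = 0.0387, adjusted p = 0.761 with an estimated correlation). Passing only with the block were p53 targets (median −0.05, camera adjusted p = 0.162, 0.00535 with the block), heat shock genes (−0.07, camera adjusted p = 0.0587, 0.0265 with the block), synaptic vesicle genes (−0.05, camera adjusted p = 0.0587, 0.0112 with the block), immediate early genes (0.15, camera adjusted p = 0.0887, 0.047 with the block) and proliferation markers (0.14, camera adjusted p = 0.0689, 0.0284 with the block). In all 18 genes passed, 1 up and 17 down (5.56% up), and 339 with the block, 83 up and 256 down (24.5% up). The count was 0 without replicate 1 or replicate 3, 5 without GNE-495 + PTX replicate 2 and 8 without GNE-495 + DMSO replicate 1. These counts are edgeR's. In the full data 891 genes had an unadjusted p under 0.05, fewer than chance gives (2231 with the block).

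JNK-IN-8 + PTX against JNK-IN-8 + DMSO showed the paclitaxel effect in the presence of the JNK inhibitor. The 10 genes that passed, all up, were tubulin genes or tubulin pseudogenes. TUBB4B rose from 109.7 ± 7.81 to 293 ± 25.2 CPM (SD, n = 3), a change of 1.42 ± 0.11 (adjusted p = 2.81e-05). The others were TUBA1B (1.23 ± 0.15), TUBB (0.98 ± 0.13), TUBA1C (0.94 ± 0.12), TUBA1A (0.83 ± 0.13) and TUBB3 (0.70 ± 0.10), TUBG1 (0.70 ± 0.08), a gamma-tubulin, and the pseudogenes TUBAP2 (1.17 ± 0.15), TUBBP1 (0.96 ± 0.15) and TUBBP2 (0.87 ± 0.14), whose reads can come from the functional genes. Of the 13 tubulin genes measured, 7 rose over all genes, 12 adjusted over the list alone and 12 with the block. Their median was 0.83 ± 0.20 (camera adjusted p = 4.67e-94).

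HRK (0.06 ± 0.19), CASP3 (−0.03 ± 0.09) and JUN (−0.15 ± 0.14) did not pass with or without the block, CASP3 being named here after its values were seen and HRK standing at 2.58 ± 0.271 and 2.69 ± 0.505 CPM. Cholesterol synthesis genes had a median of −0.07 ± 0.05 (camera adjusted p = 0.278) and glial markers −0.09 ± 0.11 (camera adjusted p = 0.516), with no member passing in edgeR with or without the block in either list. Mitochondrially encoded genes had a median of 0.69 ± 0.76 (camera adjusted p = 1.99e-08, adjusted p = 0.702 with an estimated correlation), 8 of 13 passing adjusted over the list alone and none over all genes. Without the shallow library the camera adjusted p was 0.405. NRF2 targets had a median of −0.11 ± 0.06 (camera adjusted p = 0.0471, adjusted p = 0.954 with an estimated correlation), with adjusted p = 0.0753 when the shallow library was left out. Axonal transport motors had a median of 0.03 ± 0.04 (camera adjusted p = 0.027, adjusted p = 0.95 with an estimated correlation). Voltage-gated channels (0.13, camera adjusted p = 0.0884, 0.00203 with the block) passed only with the block. With the block 158 genes passed, 63 up and 95 down (39.9% up, against 100% without it), and 101 when the shallow library was left out as well. The count was 0 without replicate 1, 1 without replicate 3, 2 without JNK-IN-8 + DMSO replicate 3, 5 without JNK-IN-8 + DMSO replicate 2 and 6 without JNK-IN-8 + PTX replicate 1 or JNK-IN-8 + PTX replicate 3. These counts are edgeR's, and 1535 genes of the full data had an unadjusted p under 0.05.

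**Figure D3:**
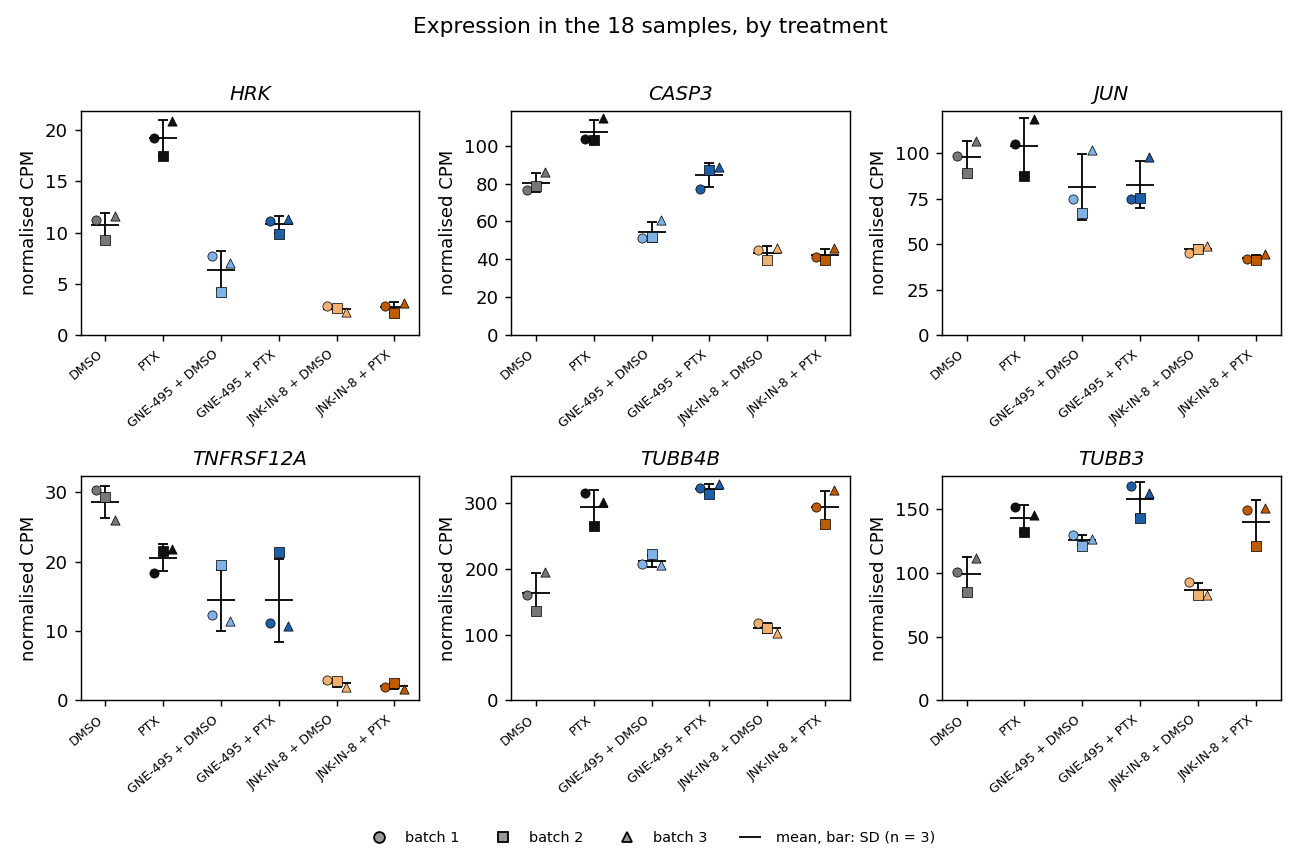
Normalised CPM of 6 genes in the 18 samples, by treatment, each point a sample with its shape for the batch, bars the mean and SD (n = 3). HRK stands at 19.2 CPM with paclitaxel, 10.8 CPM with GNE-495 + PTX and 2.69 CPM with JNK-IN-8 + PTX, and TUBB4B stands at 294, 322 and 293 CPM.

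GNE-495 + PTX against PTX asked what the STE20 inhibitor did in paclitaxel. HRK fell from 19.2 ± 1.74 to 10.8 ± 0.815 CPM (SD, n = 3), a change of −0.83 ± 0.18 (adjusted p = 0.0462, 0.0539 when the shallow library was left out, 0.487 without replicate 1, 0.771 without replicate 3, 0.000161 with the block). Among the largest rises were GDA (2.96 ± 0.22), PLA2G3 (2.87 ± 0.39), FABP3 (2.73 ± 0.50), PCSK9 (2.58 ± 0.41), LIPG (2.52 ± 0.33) and ACAT2 (2.08 ± 0.12), STARD4 (1.84 ± 0.19) and DHCR7 (1.82 ± 0.17), the last enzyme of cholesterol synthesis. Falls included PMEPA1 (−0.80 ± 0.16), ARSI (−0.76 ± 0.17), MYCBP (−0.75 ± 0.14), a MYC-binding protein, ITGB5 (−0.59 ± 0.12), an integrin, ANOS1 (−0.54 ± 0.11), an extracellular matrix protein, and MMP14 (−0.53 ± 0.10), a membrane metalloprotease. PPP1R26-AS1 (−0.61 ± 0.13) fell too (adjusted p = 0.034, 0.134 without the filter on low counts), an antisense gene whose value is uncertain. None of these falls passed without replicate 1 or replicate 3.

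Of 23 cholesterol synthesis genes, 22 rose over all genes and 23 adjusted over the list alone. The median of the list was 1.47 ± 0.17 (camera adjusted p = 1.16e-204), LSS (1.74 ± 0.13), FDFT1 (1.50 ± 0.13) and FDPS (1.56 ± 0.13) among them. NRF2 targets had a median of 0.34 ± 0.05 (camera adjusted p = 2.29e-13, adjusted p = 0.0936 with an estimated correlation). Of the 16 members, 2 rose over all genes, 8 adjusted over the list alone and 10 with the block, with G6PD (0.60 ± 0.07) and ME1 (0.73 ± 0.13). Lysosome and autophagy genes had a median of 0.15 ± 0.02 (camera adjusted p = 1.05e-07, adjusted p = 0.291 with an estimated correlation). Of their 22 genes, 1 rose over all genes, 4 adjusted over the list alone and 11 with the block, NEU1 (0.83 ± 0.15) being the member that rose. Among apoptosis genes, 1 fell over all genes, 2 adjusted over the list alone and 3 with the block. The list median was −0.05 ± 0.03 (camera adjusted p = 0.0273, 0.0809 with the block, adjusted p = 0.304 with an estimated correlation), and CASP3 (−0.35 ± 0.08) had adjusted p = 0.085 and 0.000283 with the block. Inflammatory cytokine genes had a median of −0.42 ± 0.20 (camera adjusted p = 2.15e-05). Of these 10 members, 0 fell over all genes in edgeR, 2 adjusted over the list alone and 3 with the block. Wnt targets had a median of −0.21 ± 0.06 (camera adjusted p = 0.00264). Of the 12 genes, 0 fell over all genes in edgeR, 2 adjusted over the list alone and 3 with the block.

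Immediate early genes (14 measured, median −0.17), ER chaperones (16, −0.10) and YAP-TEAD targets (22, −0.20) were lower. Of the last, AMOTL2 (−0.31 ± 0.05) passed with the block. In that order, camera adjusted p was 0.00455, 0.00392 and 0.00698, and 0.291, 0.769 and 0.755 with an estimated correlation. Axon injury genes passed only with the block (median −0.16, camera adjusted p = 0.0699, 0.0235 with the block). Tubulins (0.09 ± 0.05, camera adjusted p = 0.342) did not pass, and glial markers (0.02 ± 0.03, camera adjusted p = 0.649) did not either, with FABP7 (0.92 ± 0.13) the single glial gene that rose. JUN (−0.33 ± 0.14) passed with the block (adjusted p = 0.493, 0.0149 with it). In all 199 genes passed, 179 up and 20 down (89.9% up), and 1636 with the block, 868 up and 768 down (53.1% up). The count was 8 (8 up and 0 down) without replicate 1, 27 (27 up and 0 down) without replicate 3, 76 without GNE-495 + PTX replicate 3, 87 without PTX replicate 2, 118 without PTX replicate 1, 125 without PTX replicate 3 and 131 without GNE-495 + PTX replicate 1.

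JNK-IN-8 + PTX against PTX asked the same of the JNK inhibitor. HRK fell from 19.2 ± 1.74 to 2.69 ± 0.505 CPM (SD, n = 3), a change of −2.84 ± 0.20, CASP3 from 107 ± 6.55 to 42.4 ± 3.11 CPM (−1.34 ± 0.09) and JUN by 1.29 on the log2 scale. TXNIP (−3.34 ± 0.25), the thioredoxin-interacting protein, TNFRSF12A (−3.31 ± 0.29), CLDN4 (−3.29 ± 0.40) and SERPINE1 (−3.29 ± 0.26) fell most, with MSTN (−3.15 ± 0.37), KRTAP5-AS1 (−3.14 ± 0.18), IQGAP3 (−3.04 ± 0.40) and KRT19 (−2.90 ± 0.45). Rises were led by GDA (4.89 ± 0.23), PLA2G3 (4.29 ± 0.41), SLCO4C1 (3.95 ± 0.45), LIPG (3.60 ± 0.34) and PCSK9 (3.53 ± 0.42), TMEM97 (3.19 ± 0.16) and DERL3 (3.15 ± 0.15) and ACSS2 (2.94 ± 0.16), which makes acetyl-CoA from acetate.

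Of 20 apoptosis genes, 2 rose and 7 fell over all genes, and 2 and 9 adjusted over the list alone. Their median was −0.20 ± 0.10 (camera adjusted p = 0.00697, adjusted p = 0.201 with an estimated correlation), and BCL2L11 (1.62 ± 0.15) rose against the rest. Of 23 axon injury genes, 2 rose and 11 fell over all genes, 2 and 11 adjusted over the list alone, and 4 and 14 with the block. The median of the list was −0.31 ± 0.08 (camera adjusted p = 0.00257, adjusted p = 0.201 with an estimated correlation), HSPB1 (−1.03 ± 0.10), a small heat shock protein of neurons, among them. Inflammatory cytokine genes had a median of −0.97 ± 0.27 (camera adjusted p = 0.00133). Of their 10 members, 5 fell over all genes and 6 adjusted over the list alone, with CXCL8 (−4.02 ± 0.54), LIF (−1.96 ± 0.38) and ICAM1 (−1.25 ± 0.25). ER chaperones had a median of −0.26 ± 0.11 (camera adjusted p = 0.0118, adjusted p = 0.561 with an estimated correlation). Of these 16 genes, 1 rose and 8 fell over all genes, and 1 and 9 adjusted over the list alone, with CRELD2 (−0.51 ± 0.08) and CALR (−0.50 ± 0.10). Proliferation markers had a median of −1.23 ± 0.19 (camera adjusted p = 5.37e-05, adjusted p = 0.441 with an estimated correlation). Of the 12 members, 9 fell over all genes and 10 adjusted over the list alone, with AURKB (−2.03 ± 0.44), BIRC5 (−1.85 ± 0.31) and CDK1 (−1.59 ± 0.34). YAP-TEAD targets had a median of −0.30 ± 0.17 (camera adjusted p = 0.0421, adjusted p = 0.561 with an estimated correlation). Of their 22 genes, 3 rose and 7 fell over all genes, 3 and 8 adjusted over the list alone, and 4 and 11 with the block, with AMOTL2 (−1.07 ± 0.09) and AXL (−0.85 ± 0.11).

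In cholesterol synthesis 23 rose over all genes and 23 adjusted over the list alone. The list median was 1.69 ± 0.10 (camera adjusted p = 2.33e-66), ACAT2 (2.74 ± 0.13), LSS (1.97 ± 0.13) and DHCR24 (2.15 ± 0.16) among them. NRF2 targets had a median of 0.54 ± 0.08 (camera adjusted p = 1.12e-09, adjusted p = 0.201 with an estimated correlation). Of these 16 members, 11 rose and 0 fell over all genes, 11 and 0 adjusted over the list alone, and 13 and 1 with the block. Integrated stress response genes had a median of 0.64 ± 0.24 (camera adjusted p = 0.00322, adjusted p = 0.581 with an estimated correlation). Of the 23 genes, 5 rose over all genes, 5 adjusted over the list alone and 17 with the block, with SLC7A11 (1.53 ± 0.40), PSAT1 (1.08 ± 0.35) and PHGDH (0.93 ± 0.24), genes of cystine uptake and serine synthesis. Synaptic vesicle genes had a median of 0.28 ± 0.15 (camera adjusted p = 0.00263, adjusted p = 0.502 with an estimated correlation). Of their 19 members, 6 rose and 0 fell over all genes, 7 and 0 adjusted over the list alone, and 11 and 1 with the block, with SV2A (1.22 ± 0.16), SNCA (0.91 ± 0.16) and SNAP25 (0.74 ± 0.15). Wnt targets had a median of 0.61 ± 0.03 (camera adjusted p = 0.0122, adjusted p = 0.113 with an estimated correlation). Of these 12 genes, 3 rose over all genes, 6 adjusted over the list alone and 8 with the block. Sensory neuron identity genes had a median of 0.30 ± 0.04 (camera adjusted p = 0.0777, 0.00734 with the block). Of the 22 members, 6 rose and 2 fell over all genes, 7 and 2 adjusted over the list alone, and 12 and 6 with the block, with ISL1 (0.81 ± 0.09), NTRK2 (0.62 ± 0.08) and POU4F1 (0.62 ± 0.13) and TAC1 (−1.49 ± 0.25). The neurofilament and axon cytoskeleton list had a median of 0.33 ± 0.02 (camera adjusted p = 0.0953). Of its 11 genes, 7 rose and 1 fell over all genes, 7 and 3 adjusted over the list alone, and 7 and 4 with the block, with NEFM (0.82 ± 0.12) and ANK2 (0.38 ± 0.07).

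Mitochondrially encoded genes had a median of 0.88 ± 0.78 (camera adjusted p = 0.00322, adjusted p = 0.502 with an estimated correlation). Of these 13 members, 7 rose over all genes and 10 adjusted over the list alone. When the shallow library was left out, 4 rose over all genes and the camera adjusted p was 0.0895. Glial and Schwann cell markers had a median of 0.14 ± 0.08 (camera adjusted p = 0.0404, 0.214 with the block, adjusted p = 0.502 with an estimated correlation). Of the 10 genes, 3 rose and 0 fell over all genes, 3 and 1 adjusted over the list alone, and 5 and 2 with the block, with FABP7 (1.66 ± 0.13) and MBP (1.19 ± 0.31). Tubulins stood at nearly the same level as with paclitaxel alone, with a median of 0.00 ± 0.08, and 0 rose and 2 fell over all genes, 0 and 1 adjusted over the list alone, and 3 and 3 with the block (camera adjusted p = 0.75). Those that fell were TUBB6 (−1.02 ± 0.19) and TUBA1B (−0.43 ± 0.15), and without the shallow library 1 did, TUBA1B having adjusted p = 0.054. In all 6028 genes passed, 2863 up and 3165 down, and with the block 10289, 4974 up and 5315 down. The count was 2322 without replicate 3 and 3239 without replicate 1.

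The differences between the paclitaxel effects themselves were tested as interactions. HRK, for which paclitaxel effects were 0.84 ± 0.18 alone, 0.77 ± 0.18 under GNE-495 and 0.06 ± 0.19 under JNK-IN-8, differed by −0.07 ± 0.26 for GNE-495 (adjusted p = 1.0) and by −0.79 ± 0.27 for JNK-IN-8 (adjusted p = 1.0). CASP3 differed by 0.21 ± 0.12 and −0.45 ± 0.12 (adjusted p = 1.0 and 1.0, 0.0238 for the latter with the block). With the block, the GNE-495 difference passed for RASA4CP (−1.20 ± 0.18), RGS7BP (−1.17 ± 0.20), CENPI (−0.87 ± 0.15) and PER3 (−0.78 ± 0.12) among the largest of 14 genes in all, 0 up and 14 down. The JNK-IN-8 difference passed with the block for 54 genes, 6 up and 48 down. Of these, ACAT2 (0.90 ± 0.09), LAYN (0.73 ± 0.13) and SLC5A3 (0.42 ± 0.08) had the positive sign and PI15 (−1.29 ± 0.24), SCN4B (−0.95 ± 0.17) and SMIM5 (−0.94 ± 0.17) the negative one. The choice of these genes from the blocked fit was made after the values were seen. Without the block edgeR called 0 genes for either inhibitor, and DESeq2 0 for GNE-495 and 4 for JNK-IN-8. In edgeR 496 and 940 genes had an unadjusted p under 0.05, fewer than chance gives (1629 and 3143 with the block).

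Tubulins differed by −0.24 ± 0.23 under GNE-495 (camera adjusted p = 6.68e-05, adjusted p = 0.978 with an estimated correlation), where none passed in edgeR over all genes or adjusted over the list alone, and by 0.39 ± 0.41 under JNK-IN-8 (camera adjusted p = 1.3e-10, adjusted p = 0.19 with an estimated correlation), where 0 rose over all genes in edgeR and 3 adjusted over the list alone. Glial and Schwann cell markers differed by −0.24 ± 0.06 (camera adjusted p = 0.000505, adjusted p = 0.978 with an estimated correlation) and −0.48 ± 0.02 (camera adjusted p = 7.8e-09, adjusted p = 0.19 with an estimated correlation). Cholesterol synthesis genes differed under JNK-IN-8 by 0.23 ± 0.18 (camera adjusted p = 2.62e-07, adjusted p = 0.563 with an estimated correlation), with ACAT2 the member that passed with the block, and by 0.06 ± 0.08 under GNE-495 (camera adjusted p = 0.758). Inflammatory cytokine genes differed under JNK-IN-8 by 0.37 ± 0.17 (camera adjusted p = 0.038, 0.0546 with the block, adjusted p = 0.253 with an estimated correlation). Mitochondrially encoded genes differed under JNK-IN-8 by 0.58 ± 0.91 (camera adjusted p = 0.000124, adjusted p = 0.481 with an estimated correlation), with adjusted p = 0.704 when the shallow library was left out.

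To compare the size of the paclitaxel response without reusing the samples that chose the genes, genes with an absolute log2 fold change of at least 1 were called in 2 batches and measured in the batch left out. Without the block, genes passed only with batch 2 left out, so these values have no error over batches. There, 5 genes rose, with medians of 0.55 alone, 0.00 under GNE-495 and −0.27 under JNK-IN-8, and 1 fell, at −0.46, −0.45 and −0.26. With the block and no minimum fold change, a pair of choices added after the values were seen, genes passed with each batch left out (7, 779 and 11 rose without batch 1, 2 and 3, and 1, 563 and 3 fell). Those that rose had mean medians of 0.39 ± 0.22 alone, 0.32 ± 0.29 under GNE-495 and 0.37 ± 0.68 under JNK-IN-8 (SD over batches, n = 3), and those that fell −0.54 ± 0.52, −0.32 ± 0.28 and 0.00 ± 0.04. For the 274 genes that rose and the 204 that fell with paclitaxel alone in the blocked fit, chosen on the same samples, the medians without inhibitor were 0.44 and −0.31. Under GNE-495 they were 0.15 and −0.17, with 91.6% and 91.2% of the genes keeping their sign. Under JNK-IN-8 they were 0.01 and −0.07, with 52.6% and 71.6%. Medians of genes chosen and measured on the same samples cannot be set against each other as sizes.

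**Figure D4:**
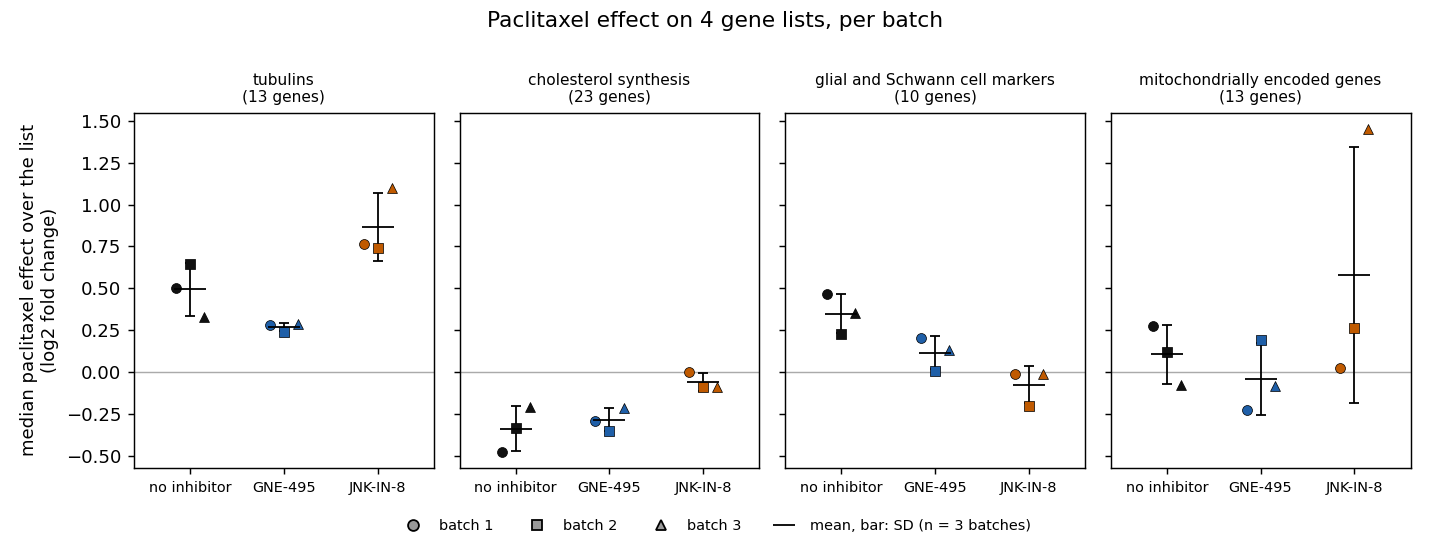
Median paclitaxel effect (log2 fold change, vertical axis) over the members of 4 gene lists without inhibitor, with GNE-495 and with JNK-IN-8, 1 point per batch, bars the mean and SD over the 3 batches. Tubulin medians lie above 0 in every batch and arm, and the mitochondrial value of batch 3 with JNK-IN-8 (1.45) is that of the sample with the shallow library.

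GNE-495 + PTX against JNK-IN-8 + PTX set the inhibitors side by side in paclitaxel. HRK was higher with GNE-495 (2.01 ± 0.19), as were CASP3 (1.00 ± 0.09) and JUN (0.96 ± 0.14), while BCL2L11 (−1.88 ± 0.16) was lower. The largest differences were in CLDN4 (3.07 ± 0.40), KRT19 (3.06 ± 0.45), a keratin, IQGAP3 (3.02 ± 0.40), SERPINE1 (2.90 ± 0.26) and KRTAP5-AS1 (2.87 ± 0.17) upward. Downward they were in CEMIP (−3.32 ± 0.43), which degrades hyaluronan, SERTM1 (−3.08 ± 0.35), SP5 (−2.90 ± 0.28), a Wnt target, and HS6ST3 (−2.59 ± 0.43), a heparan sulfate sulfotransferase.

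Wnt targets were lower with GNE-495 (median −0.75 ± 0.07, camera adjusted p = 4.44e-05). Of 12 genes, 5 fell over all genes and 6 adjusted over the list alone, with AXIN2 (−1.24 ± 0.15), NKD1 (−1.55 ± 0.21) and LGR5 (−2.51 ± 0.57). Proliferation markers were higher (median 1.35 ± 0.59, camera adjusted p = 2.68e-05, adjusted p = 0.543 with an estimated correlation). Of 12 genes, 10 rose over all genes and 10 adjusted over the list alone, with AURKB (2.19 ± 0.44) and MKI67 (1.77 ± 0.36). Cholesterol synthesis genes were lower (median −0.30 ± 0.15, camera adjusted p = 0.000533, adjusted p = 0.607 with an estimated correlation). Of 23 genes, 6 fell over all genes, 6 adjusted over the list alone and 15 with the block, with ACAT2 (−0.66 ± 0.12) and HMGCR (−0.71 ± 0.16). Axon injury genes were higher (median 0.23 ± 0.11, camera adjusted p = 0.0261, adjusted p = 0.543 with an estimated correlation). Of 23 genes, 5 rose and 3 fell over all genes, 8 and 3 adjusted over the list alone, and 12 and 6 with the block, with TNFRSF12A (2.80 ± 0.28) and HSPB1 (1.31 ± 0.10). For apoptosis genes the median was 0.16 ± 0.07 (camera adjusted p = 0.0799, 0.0181 with the block). Of these 20 genes, 7 rose and 3 fell over all genes, and 9 and 3 adjusted over the list alone. Lower medians were found for NRF2 targets (16 measured, median −0.24, camera adjusted p = 0.00866, adjusted p = 0.605 with an estimated correlation), integrated stress response genes (23 measured, median −0.52, camera adjusted p = 0.0115, adjusted p = 0.617 with an estimated correlation), synaptic vesicle genes (19 measured, median −0.19, camera adjusted p = 0.018, adjusted p = 0.607 with an estimated correlation), sensory neuron identity genes (22 measured, median −0.28, camera adjusted p = 0.040, adjusted p = 0.543 with an estimated correlation) and immediate early genes (14 measured, median −0.53, camera adjusted p = 0.040, 0.133 with the block, adjusted p = 0.543 with an estimated correlation). Lysosome and autophagy genes were higher (median 0.14 ± 0.05), and 7 rose and 2 fell over all genes, 8 and 2 adjusted over the list alone, and 13 and 3 with the block (camera adjusted p = 0.0391, adjusted p = 0.607 with an estimated correlation, adjusted p = 0.0527 when the shallow library was left out). For mitochondrially encoded genes the median was −0.69 ± 0.80 (camera adjusted p = 0.0214, 0.12 with the block, adjusted p = 0.607 with an estimated correlation, adjusted p = 0.323 without the shallow library), 5 falling with it and 1 without it. In all 5714 genes passed, 2970 up and 2744 down, and with the block 9674, 4906 up and 4768 down. The count was 2194 without replicate 3 and 3329 without replicate 1.

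Overlaps were counted only between comparisons that share no library. Of 305 genes that rose with GNE-495 alone, 267 also rose with JNK-IN-8 in paclitaxel, against 35.7 by chance, and of 86 that fell, 51 also fell, against 11.1. Across genes, which are not independent replicates, Pearson's r was 0.31 and Spearman's rho 0.24. Of 179 genes that rose with GNE-495 in paclitaxel, 153 rose with JNK-IN-8 alone (18.3 by chance), and of 20 that fell, 9 fell (2.21 by chance), with r = 0.18 and rho = 0.15. For paclitaxel, 22 genes rose (0.931 by chance) and 59 fell (2.14 by chance) both alone and under GNE-495 in the fits with the block (r = 0.15, rho = 0.20). The matching numbers with JNK-IN-8 were 17 (0.706 by chance) and 5 (0.793 by chance), with r = 0.05 and rho = 0.07.

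The kinases that the inhibitors act on, and further genes named in advance, were followed in every comparison. With JNK-IN-8 alone, MAP4K4 (0.36 ± 0.07) rose and TNIK (−0.27 ± 0.06) fell, both STE20 kinases targeted by GNE-495, while MINK1 (0.19 ± 0.08) had adjusted p = 0.102 (0.00135 with the block). Of 19 genes of the MAP4K and JNK cascade, with JNK-IN-8 alone 3 rose and 3 fell over all genes, 3 and 3 adjusted over the list alone, and 7 and 5 with the block (camera adjusted p = 0.987) and, with JNK-IN-8 in paclitaxel, 5 rose and 3 fell over all genes, 6 and 4 adjusted over the list alone, and 9 and 4 with the block (camera adjusted p = 0.52). MAPK9 (0.29 ± 0.06) and MAPK10 (0.49 ± 0.12), coding for JNK2 and JNK3, rose in the latter, and MAPK8 had a value of 0.22 ± 0.07 (adjusted p = 0.0398, 0.104 without the filter on low counts). With GNE-495 in paclitaxel the values of MAP4K4 (−0.13 ± 0.07), MINK1 (0.12 ± 0.08) and TNIK (−0.19 ± 0.06) had adjusted p = 0.625, 0.773 and 0.218 (0.0141 with the block). SARM1, whose enzyme degrades NAD in injured axons, fell with JNK-IN-8 alone (−0.39 ± 0.05) and in paclitaxel (−0.39 ± 0.05), and NMNAT2, the axonal NAD-synthesising enzyme, had values of 0.08 ± 0.09 and 0.29 ± 0.09 (adjusted p = 0.608 and 0.0298, the latter 0.0525 without the filter). MAP3K12, coding for the axon injury kinase DLK, had values of −0.08 ± 0.06 with paclitaxel, 0.05 ± 0.06 with GNE-495 in paclitaxel and −0.02 ± 0.06 with JNK-IN-8 in paclitaxel (adjusted p = 1.0, 0.927 and 0.805).

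For paclitaxel alone, GNE-495 in paclitaxel and JNK-IN-8 in paclitaxel in that order, the values were ATF3 (−0.15 ± 0.49, −0.27 ± 0.49 and 0.30 ± 0.49), an injury-induced transcription factor, DDIT3 (−0.15 ± 0.38, −0.07 ± 0.38 and −0.01 ± 0.38), a stress-induced transcription factor, BBC3 (0.03 ± 0.24, 0.09 ± 0.24 and −0.03 ± 0.24), coding for the BH3-only protein PUMA, CDKN1A (−0.24 ± 0.29, 0.22 ± 0.29 and −0.49 ± 0.30), the p53 target p21, and GAP43 (−0.18 ± 0.09, 0.18 ± 0.09 and 0.07 ± 0.09), a growth cone protein. The adjusted p of these values was 1.0, 0.963 and 0.711 for ATF3, 1.0, 0.995 and 0.99 for DDIT3, and 1.0, 0.981 and 0.957 for BBC3. For CDKN1A it was 1.0 (0.0318 with the block), 0.941 (0.0176 with the block) and 0.254 (9.85e-07 with the block), and for GAP43 1.0, 0.625 (0.0447 with the block) and 0.63. SPRR1A, an axon regeneration gene, had too few counts to be tested.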

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

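Of the tests in this part, those of the interactions and the sum over tubulin copies were planned, and the others were chosen only after the results were seen. In 24 sets of 6 libraries (4 measures in each of the 6 groups), 5 had a library far from the rest by Dixon's ratio, where chance gives about 1 in 20. Total counts set apart the shallow library (7448989, the nearest other at 35535991) and technical replicate 1 of GNE-495 + PTX replicate 2 (35452116, the nearest at 41819574). The percent of counts from mitochondrially encoded genes set apart technical replicate 2 of GNE-495 + DMSO replicate 1 (0.398%, the nearest at 0.31%) and the shallow library (2.14%, the nearest at 0.445%). The percent of counts from ribosomal RNA genes set apart the shallow library (1.44%, the nearest at 0.0908%).

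The paclitaxel effect differed between arms for 17 list and inhibitor combinations by the camera test of the interaction, given here as medians of the differences (log2). For GNE-495 they were ER chaperones (−0.0949), tubulins (−0.24), voltage-gated channels (0.11) and glial and Schwann cell markers (−0.24). For JNK-IN-8 they were ER chaperones (−0.13), tubulins (0.39), microtubule-associated proteins (0.12), axonal transport motors (0.15), neurofilament and axon cytoskeleton genes (0.12), sensory neuron identity genes (0.19), voltage-gated channels (0.16), synaptic vesicle genes (0.15), cholesterol synthesis (0.23), inflammatory cytokines (0.37), mitochondrially encoded genes (0.58), glial and Schwann cell markers (−0.48) and proliferation markers (−0.42). None of the 17 passed with an estimated correlation, where the adjusted p was 0.978 for GNE-495 and 0.19 to 0.563 for JNK-IN-8.

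Cholesterol synthesis genes were higher with both inhibitors, with medians of 1.36 for GNE-495 and 1.55 for JNK-IN-8 without paclitaxel and 1.47 and 1.69 with it. A larger share of another listed cell type would raise its markers at least as much, but the smallest gap to the highest marker list was 0.426 (log2; the 4 melanocyte markers at 1.12 with JNK-IN-8 alone, where PMEL, the most abundant, changed by 0.19 ± 1.12), above the sum of the SDs (0.285). A batch of libraries as the cause would leave a batch without the rise, and the lowest of the 12 batch medians was 1.19. The amount of vehicle in the inhibitor groups is not labelled, so it stays open and untested. A candidate explanation is a response of the cells to both compounds, through a shared target or otherwise, which these data cannot separate.

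For tubulin genes the paclitaxel effects under JNK-IN-8 and without inhibitor differed by a median of 0.39 ± 0.41, within its spread, with 0 genes called in edgeR and camera adjusted p = 1.3e-10, adjusted p = 0.19 with an estimated correlation. The shallow library is not the cause, since without it the difference in its batch was 0.73. Reads that moved between tubulin copies and pseudogenes cannot be told apart from a true difference: in the summed counts of 59 tubulin genes and pseudogenes it was 0.33 ± 0.40 (0.24, −0.01 and 0.76 in the batches), within its spread. The values are also consistent with a lower level before paclitaxel and a common level after it, as the median was −0.33 ± 0.19 for JNK-IN-8 alone and −0.00224 for JNK-IN-8 in paclitaxel. That reading may hold as a hypothesis only, since it was formed and tested on the same samples.

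Mitochondrially encoded genes were higher in JNK-IN-8 + PTX, the medians of the paclitaxel effect under JNK-IN-8 being 0.03, 0.26 and 1.45 in the batches. Without the shallow library the median of batch 3 was 0.0241, so this library likely carried the pattern. No biological explanation was tested.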

How the results depend on the processing

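The alternatives that leave out the shallow library, with or without the block, that with 6 blocks, the choice of genes from the blocked fit and the last alternative for the response size were added after the data were seen. Counts of genes are given in the order paclitaxel alone, GNE-495 alone, JNK-IN-8 alone, paclitaxel under GNE-495, paclitaxel under JNK-IN-8, GNE-495 in paclitaxel, JNK-IN-8 in paclitaxel, the GNE-495 interaction, the JNK-IN-8 interaction and GNE-495 against JNK-IN-8 in paclitaxel. As reported, edgeR called 2, 391, 5199, 18, 10, 199, 6028, 0, 0 and 5714 genes, with 1111, 2338, 7994, 891, 1535, 2187, 8786, 496, 940 and 8416 at an unadjusted p under 0.05.

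With the block the counts were 478, 2063, 9369, 339, 158, 1636, 10289, 14, 54 and 9674, and with the shallow library left out as well 461, 2016, 9297, 333, 101, 1577, 10031, 16, 48 and 9430. With each library as a sample and 6 blocks of batch and technical number they were 1395, 2963, 10090, 635, 1759, 2875, 10996, 83, 995 and 10450, and without blocks 62, 981, 6911, 134, 17, 720, 7984, 5, 3 and 7566, both taking technical libraries as independent. The block removes the differences between batches, as its lower coefficient of variation shows. It ended the call of 2 of 6028 genes for JNK-IN-8 in paclitaxel and 1 of 5714 for GNE-495 against JNK-IN-8, and of no other gene called in the 10 comparisons.

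DESeq2 gave 50, 681, 5725, 104, 37, 449, 6523, 0, 4 and 6235, the groups of each comparison alone 0, 200, 4516, 0, 1, 48, 4096, 0, 0 and 3332, and technical replicate 1 alone 0, 184, 2822, 4, 1, 88, 3461, 0, 0 and 2828. For these the cause was not tested, except that the latter pair use fewer samples or lower depth. A minimum log2 fold change of 1, which can only lower a count, gave 0, 122, 1360, 5, 3, 74, 1407, 0, 0 and 1140. Technical replicate 2 alone gave 10 for paclitaxel alone and 41 for paclitaxel under GNE-495. Without a filter on low counts the count was 40 for paclitaxel under GNE-495, and with a mean CPM of at least 1 it was 46 for paclitaxel under GNE-495, causes not tested. All other counts under these settings, and all 10 with DESeq2's size factors or without the shallow library, stayed within 1.5 times the reported ones. Leaving out 1 sample, or 1 replicate in all groups, gave ranges of 0 to 54, 96 to 436, 1908 to 4904, 0 to 21, 0 to 10, 8 to 243, 2322 to 5487, 0 in every case, 0 in every case and 2194 to 4929.

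No test of a named gene or list that was called reversed its direction under these alternatives. For paclitaxel under JNK-IN-8 the calls went from 10 up and 0 down to 63 up and 95 down with the block. Of 276 named genes and comparisons, 46 passed only with the block and 21 only with DESeq2, and none lost its call with either. Without replicate 1, 2 and 3, 71, 12 and 68 no longer passed, and 6, 3 and 2 that were not called changed sign, as did 1 without the shallow library. Calls given above ended for EGR1 with DESeq2's size factors and for PPP1R26-AS1, MAPK8 and NMNAT2 without the filter. Those of HRK and TUBA1B ended without the shallow library. Over 310 tests of lists, camera called 100, of which 86 no longer passed with an estimated correlation. Those that did were tubulins for paclitaxel alone and under JNK-IN-8, cholesterol synthesis and inflammatory cytokines for both inhibitors with and without paclitaxel, NRF2 targets for GNE-495 alone, and Wnt targets for GNE-495 alone, in paclitaxel and against JNK-IN-8. With fry 63 no longer passed and 20 did newly, and with the block 7 and 15. Among lists that were not called, 12 changed sign with the block and 3 with fry. The shallow library's removal ended 6 list calls. Median, mean and test differed in sign in 39 of the tests, none of them called.

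For the size of the paclitaxel response, each alternative that changed 1 choice again gave genes with batch 2 left out alone, so these have no spread. Without the minimum fold change, 46 genes rose with medians of 0.34, 0.03 and −0.18 (alone, under GNE-495 and under JNK-IN-8) and 8 fell with −0.51, −0.28 and −0.01. With genes chosen in the blocked fit, 25 rose with 0.51, 0.00 and −0.24 and 27 fell with −0.42, −0.02 and 0.07. Means over genes were 0.66, 0.09 and −0.23 for the 5 rising genes as reported. With the block and no minimum together, medians for the rising genes under JNK-IN-8 were 0.12, −0.15 and 1.13 with batch 1, 2 and 3 left out, from 7, 779 and 11 genes.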

Other observations

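The splits of samples in this part were planned, and the lists below were chosen only after their results were seen. Other splits of the same samples were counted for every comparison. For the 8 comparisons of a pair of groups, 3 samples against 3 make 10 splits, too few for a share under 0.05. The real split, 1 of the 10, gave the reported counts and the others 0 in edgeR in each. The block allows 4 splits within batches. The real split (1 of the 4) gave the counts with the block and the others 0 in each.

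For the interactions without the block the splits say nothing of chance: with a real count of 0 for either inhibitor, all 100 drawn splits reach it by definition. The highest other count was 4 for GNE-495 and 5 for JNK-IN-8. With the block, 6 of 32 splits gave at least the real 14 genes for GNE-495. Splits that swap the labels in only some batches of 1 arm keep part of the paclitaxel effect. Their counts do not measure chance alone, so chance can be neither excluded nor inferred from them. For JNK-IN-8, 2 of 32 gave at least the real 54, the real split and the split that swaps the labels within 1 arm in every batch. That split also gave the highest other counts, 979 and 687, and points to a structure of the samples: it adds the paclitaxel effects of both arms in place of subtracting them. Without it, 5 splits for GNE-495 and 1, the real one, for JNK-IN-8 reached the real count, and the highest others were 104 and 38. That split was set aside only after the counts were seen, so whether chance explains the JNK-IN-8 count stays open.

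Of the lists not described above, interferon-stimulated genes, mesenchymal markers and progenitor and pluripotency markers did not pass in any of the 10 comparisons with or without the block. Their medians with JNK-IN-8 in paclitaxel were −0.24 ± 0.31 (15 measured, camera adjusted p = 0.27), 0.00 ± 0.07 (13 measured, 0.625) and −0.43 ± 0.08 (6 measured, 0.147). p53 targets passed for the GNE-495 interaction with the block alone (median −0.08 ± 0.05, camera adjusted p = 0.258, 0.0217 with the block), as did YAP-TEAD targets (median 0.09 ± 0.12, camera adjusted p = 0.758, 0.0324 with the block).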
